A study of Mus musculus with 6 samples.

How the data were processed

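Gene counts from 6 mouse liver libraries were analysed, 3 Control and 3 labelled as double knockouts (DKO). Per the labels' protocols, RNA was extracted with RLT buffer and RNeasy kits, and a company prepared, sequenced and processed the libraries. The deposited values are whole-number read counts per Ensembl gene ID for each library, made with STAR and HTSeq on mm10, per the submitters' processing notes. Versions, the library kit, the strand setting and the annotation release are not given in the sources used here. Because the strand setting is unknown, reads of overlapping or antisense genes cannot be told apart, and HTSeq leaves out reads that align to more than 1 place, which affects gene families such as the Saa genes.

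Each table held 43346 gene IDs and 5 rows that name no gene. These rows held 65.1% to 66.7% of reads in Control and 97.3%, 95.4% and 95.3% in DKO replicates 1, 2 and 3, and stayed out of library sizes and tests. Positions, exonic lengths and GC content came from GENCODE M21 on the same build. Gene names came from a gene name reference, which matched 42462 IDs and left 884 unmatched. For the unmatched IDs the GENCODE M21 name was used where there was one, and otherwise the ID itself. Total reads were 45427473, 41007649 and 37000776 in Control and 11562609, 11462053 and 31478146 in the DKO-labelled libraries. Wilson 95% intervals of single-library shares were at most 0.190 percentage points wide. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Groups and replicate numbers followed the sample titles. No pair of libraries held identical values, and no pair agreed within sampling noise.

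The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust fitting, TMM normalization, filterByExpr by group and Benjamini-Hochberg adjusted p under 0.05, two-sided, without covariates. CPM per gene are scaled by TMM. Gene lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry, in limma 3.58.1. Lists with fewer than 3 tested members had no list test. Library measures were compared with two-sided exact permutation tests over 20 arrangements, for which 0.1 is the smallest p. A group at 0 was set at a floor of 3 counts over its 3 libraries. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors, upper-quartile and no normalization, no filter, a filter of 1 CPM in 3 libraries, an adjusted p of 0.01, glmTreat against a fold of 1.5, removal of the 10 most counted genes, a replicate block and leaving out each library. Simulated data had 200 changed genes among 11592, at Control proportions, the spread between Control libraries and the library sizes of DKO versus Control. There edgeR recovered 52%, 94%, 98% and 100% of genes changed 2-, 4-, 8- and 16-fold, with 8 false calls. The simulation held no background reads and less spread than the real comparison (coefficient of biological variation 18.8% in Control, 63.9% over all 6 libraries). Its recovery therefore does not carry over to the real comparison.

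The 41 gene lists and the rule for named genes were fixed before the data were examined. The rule takes 17 fixed genes, the 5 highest and 5 lowest log2 fold changes past the threshold (at least 5 CPM in the higher group, no overlap between groups, no clone or predicted names), and up to 3 members per main list and 2 per other list with the smallest adjusted p. It gave 94 genes, of which the text names a part and some are not reported here, also not in the counts of named genes by setting. Members named in the comparison of single libraries, which are Cyp1a2, Saa1 and Hp, were chosen after their values were seen. Of 637 listed symbols 636 were found.

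The following steps were added after the data were examined. Background reads per kb were estimated per DKO-labelled library from 8600 protein-coding genes with at most 10 Control counts, in 10 bins of GC content, and multiplied by exonic length. Abundant liver genes were 163 nuclear protein-coding genes with over 30000 Control counts, and the median ratio to the Control mean gave each library's scale, on which the bounds of lower genes at 0 were repeated. Per-library ratios used 1806 genes with at least 3000 Control counts and a pseudocount of 0.5, and those of DKO replicate 3 were repeated without background subtraction. Matched random sets drew each gene from its 200 nearest genes in Control expression, and in expected background where stated, 10000 times. Mixtures of the Control libraries were fitted to the abundant genes of DKO replicate 2 by non-negative least squares. The smallest expectation of a mixture was the lowest of the 3 Control counts, each scaled to the abundant-gene total of DKO replicate 2 less background, over nuclear genes. Intervals of the X-to-autosome ratio came from 1000 bootstraps over genes. Further added settings were the abundant-gene scale, background subtraction, a Control level of at least 50 CPM, removal of 43 mitochondrial and ribosomal-RNA-like genes, and each DKO-labelled library alone against Control. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and the figures.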

Results

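The data were RNA-seq gene counts from the livers of C57BL6 mice aged 3 months. There were 3 Control libraries and 3 libraries labelled as hepatocyte-specific double knockouts (DKO) of β-catenin, encoded by Ctnnb1, and γ-catenin, also called plakoglobin and encoded by Jup. β-catenin anchors cadherins at cell junctions and carries the Wnt signal, and γ-catenin is its close relative at adherens junctions and desmosomes. The comparison asked what the loss of both catenins from hepatocytes does to liver transcripts, and the title of the series names hepatocyte polarity, TGFβ and HNF4α. The Control libraries held 15869639, 13953699 and 12320487 reads assigned to genes. The DKO-labelled libraries 1, 2 and 3 held 309731, 525037 and 1491237. The labels number the libraries within each group without stating that each came from a separate animal, so p-values measure only the spread between these libraries.

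Neither targeted transcript passed the threshold, although both had a lower library-scaled count (CPM) in every DKO-labelled library than in every Control library. Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, mm10) had 2945, 2896 and 2650 counts in the Control libraries and 0, 52 and 65 in the DKO-labelled ones. Its TMM-scaled level was 254.7 ± 26.5 CPM in Control and 53.3 ± 47.1 CPM in the DKO-labelled libraries (SD, n = 3 each), a log2 fold change of -2.26 (SE 1.30) with an adjusted p of 0.171 in edgeR's quasi-likelihood test. Without DKO replicate 1 the adjusted p was 0.0119. Jup (ENSMUSG00000001552, chromosome 11, 100368958 to 100397763) had 339, 270 and 196 counts in Control and 6, 1 and 11 in the DKO-labelled libraries, a log2 fold change of -1.68 (SE 0.72) with an adjusted p of 0.0847. Without DKO replicate 1 its adjusted p was 0.0434.

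Set against the abundant liver transcripts of the same library, Ctnnb1 was not low in DKO replicate 2. That gives no sign of a loss of Ctnnb1 but does not decide about the label. Undeleted exons and other cells also give reads, and carry-over of Control RNA stays open. Ctnnb1 was not low in DKO replicate 3 either, and that value does not decide about the label. Abundant genes scattered more widely there than in DKO replicate 2, and the background of a single gene is uncertain. Scaling on 163 abundant nuclear genes, chosen after the data were examined, turned the log2 fold change of Ctnnb1 to 0.89 and that of Jup to 3.90 (adjusted p = 0.0436). The Jup counts of 6, 1 and 11 were below the 10.6, 9.34 and 20.4 reads expected from background alone, so Jup transcripts were not detectable above background at this depth. In DKO replicate 2, the 52 Ctnnb1 reads compared with 53.3 expected at the Control proportion and 7.56 from background reads. In DKO replicate 3, the 65 reads compared with 15.6 expected from liver transcripts and 18.8 from background reads. In DKO replicate 1 only 1.32 were expected from liver transcripts, so its count of 0 was not informative about them. Another 10.3 were expected there from background reads, so the background estimate of a single gene can be far off. Transcripts from exons outside the deleted part, or from cells other than hepatocytes, would still be counted. Every direction below is therefore one between libraries as labelled.

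The DKO-labelled libraries contained little liver RNA. Albumin (Alb), the most abundant secreted hepatocyte protein, took 7.02% ± 0.57 of gene counts in Control (SD, n = 3). Its share was 0.0933% in DKO replicate 1 (95% Wilson interval 0.0832 to 0.105), 3.08% in replicate 2 (3.03 to 3.12) and 0.322% in replicate 3 (0.313 to 0.331). Reads assigned to genes made up 34.1% ± 0.82 of all reads in Control and 2.68%, 4.58% and 4.74% in DKO replicates 1, 2 and 3, while uniquely aligned reads outside genes made up 38.9% ± 1.51 and 66.7% ± 6.44. Mitochondrial transcripts took 6.46% ± 0.12 of gene counts in Control and 6.27%, 14.4% and 62.7% in DKO replicates 1, 2 and 3. Olfactory and vomeronasal receptor genes, 1345 genes used by sensory neurons of the nose, had a summed 11.9 ± 2.58 CPM (unscaled by TMM) in Control and 1232 ± 499 in the DKO-labelled libraries. The gene-assigned, no-gene, receptor and Alb values did not overlap between the groups, and each gave p = 0.1 in a two-sided exact permutation test (adjusted p = 0.167 over 10 measures). That is the smallest p that 3 against 3 libraries allow.

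**Figure D1:**
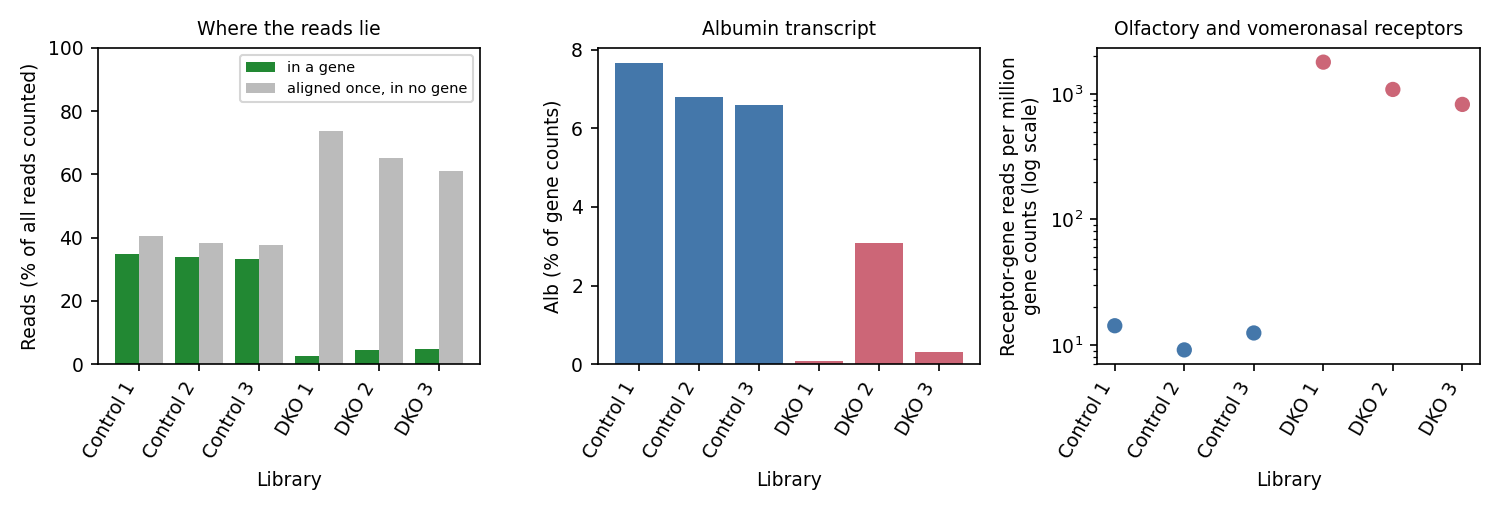
Per library, the left panel gives the percent of all reads that lay in a gene (green) or aligned uniquely outside genes (grey), the middle panel Alb as a percent of gene counts, and the right panel summed receptor-gene CPM on a log axis. Gene-assigned reads were 34.1% of reads in Control on average and 2.68% to 4.74% in the DKO-labelled libraries, with each bar or point 1 library.

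Transcripts nearly silent in Control liver accounted for most of the genes that were higher in the DKO-labelled libraries. Of 15561 genes tested, 6863 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4871 higher and 1992 lower, and each had an absolute log2 fold change of at least 1. Among the higher genes 57.3% had at most 10 counts over the 3 Control libraries. The count filter admits genes with so few Control counts only through reads in the DKO-labelled libraries, so that the 2792 tested ones, all called higher, were selected for this. The filter left out 25605 others, whose median was 0 reads over the DKO-labelled libraries against 40 in the tested ones. The lower genes had a median Control level of 34.4 CPM and the higher genes one of 0.156 CPM. Restricting the test to the 2595 genes with at least 50 CPM in Control left 0 calls in edgeR, with 523 genes at an unadjusted p under 0.05. The coefficient of biological variation was 63.9% over all 6 libraries and 18.8% among the Control libraries alone.

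The split between higher and lower genes depended on the scaling and on the libraries used. With DESeq2's size factors the same test gave 5045 higher and 3577 lower genes. DESeq2 itself gave 5486 higher and 4776 lower. Scaling on the abundant liver genes, with background reads kept, shifted the median log2 fold change of all genes by 4.76. It gave 9718 higher and 85 lower genes, with 16 moving from lower to higher. Subtracting the expected background reads gave 2301 higher and 2768 lower. Leaving out DKO replicate 2 raised the calls to 9728, 5236 higher and 4492 lower. Leaving out Control replicate 3 reduced them to 4710, and without Control replicate 1, 2 or 3 the lower genes numbered 567, 601 and 580 and the higher genes 4317, 4143 and 4130. Against Control, DKO replicate 1 alone gave 3798 higher and 7013 lower, replicate 2 alone 3869 and 4374, and replicate 3 alone 5921 and 5716. The plot of calls by Control expression gives both directions per bin.

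**Figure D2:**
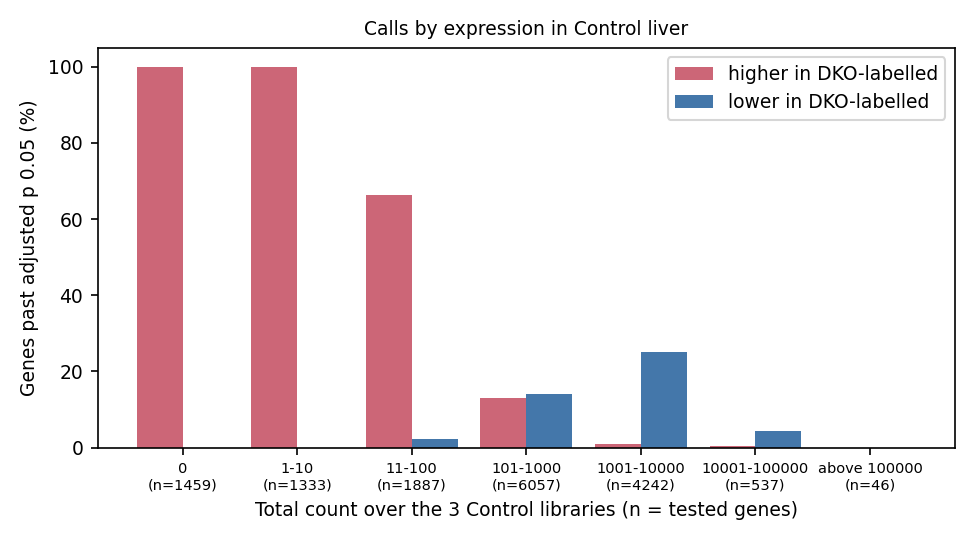
Percent of tested genes past an adjusted p of 0.05 (vertical axis), higher (red) or lower (blue) in the DKO-labelled libraries, in bins of the total count over the 3 Control libraries (horizontal axis, with the number of tested genes). Genes with at most 10 Control counts enter the test only through reads in the DKO-labelled libraries, which fixes their bars, and the split of higher and lower calls was 4871 to 1992 with TMM and 9718 to 85 when scaled on abundant liver genes.

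The largest calls were genes at 0 in every library of a group. Jph4, a junctophilin of neurons, had 347, 168 and 197 reads in the DKO-labelled libraries and none in Control, at least 3534-fold higher against a floor of 3 counts over the group. Elfn2, Cacng2, Dlx4 and Hoxc11, known from neurons or from developmental patterning, were at least 1804-fold, 1794-fold, 1569-fold and 1519-fold higher. At the other end, Gstm4, a glutathione transferase, had 572, 635 and 529 counts in Control and 0 in all DKO-labelled libraries, at least 39.8-fold lower. Dgat1, which makes triglyceride, was at least 28.0-fold lower, and Prnp, Srsf4 and Spns2 at least 27.1-fold, 25.3-fold and 25.2-fold lower. These bounds of lower genes hold with TMM scaling only, and on the abundant-gene scale they were 4.78-fold for Gstm4, 3.38-fold for Dgat1, 3.17-fold for Prnp, 3.11-fold for Srsf4 and 3.08-fold for Spns2. Each of these 10 calls held in every alternative that gave the gene a value. That adds little support, because the genes were picked as extremes and 0 reads in a whole group fix the direction. The higher ones are among the 1459 tested genes without a Control count, all of which were called higher. The bounds cover counting error only.

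Pericentral genes, which Wnt and β-catenin keep active around the central vein, had the lowest percentile among matched random sets, although the B cell and female liver lists lay farther below their matched medians. Notum, a secreted Wnt inhibitor, fell from 276, 432 and 386 counts to 0, 1 and 1, a log2 fold change of -5.22 (SE 0.95, adjusted p = 0.00175), and lost its call when scaled on the abundant genes. Glul, the glutamine synthetase of the hepatocytes next to the central vein, had a log2 fold change of -2.79 (SE 1.39, adjusted p = 0.125), and Cyp2e1 one of -3.10 (SE 2.05, adjusted p = 0.228). Both passed without DKO replicate 2, at adjusted p = 0.00429 and 0.00431. In DKO replicates 1, 2 and 3 Glul had 22, 232 and 18 counts and Cyp2e1 4, 1478 and 24. The counts of replicate 2 were close to the 220 and 1504 expected there from the best mixture of the Control libraries plus background. Neither gene was thus low against other liver transcripts in that library. The Wnt target Axin2 and the receptor Tnfrsf19 rose, by log2 fold changes of 2.51 (adjusted p = 0.0143) and 3.46 (adjusted p = 0.00394), and both calls were lost after background subtraction. The Axin2 call was also lost without Control replicate 2 (adjusted p = 0.0929) or 3 (0.0879). Of 21 tested list members 3 were higher and 3 lower, with the same numbers when adjusted over the list alone. The list median was -2.79, below the middle 95% of random sets matched on Control expression and expected background (-2.37 to -0.52). The camera test did not call the list (adjusted p = 0.132, and 0.815 with an estimated correlation). On the abundant-gene scale the median was 0.84, and camera called the list lower than other genes (adjusted p = 0.00143).

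**Figure D3:**
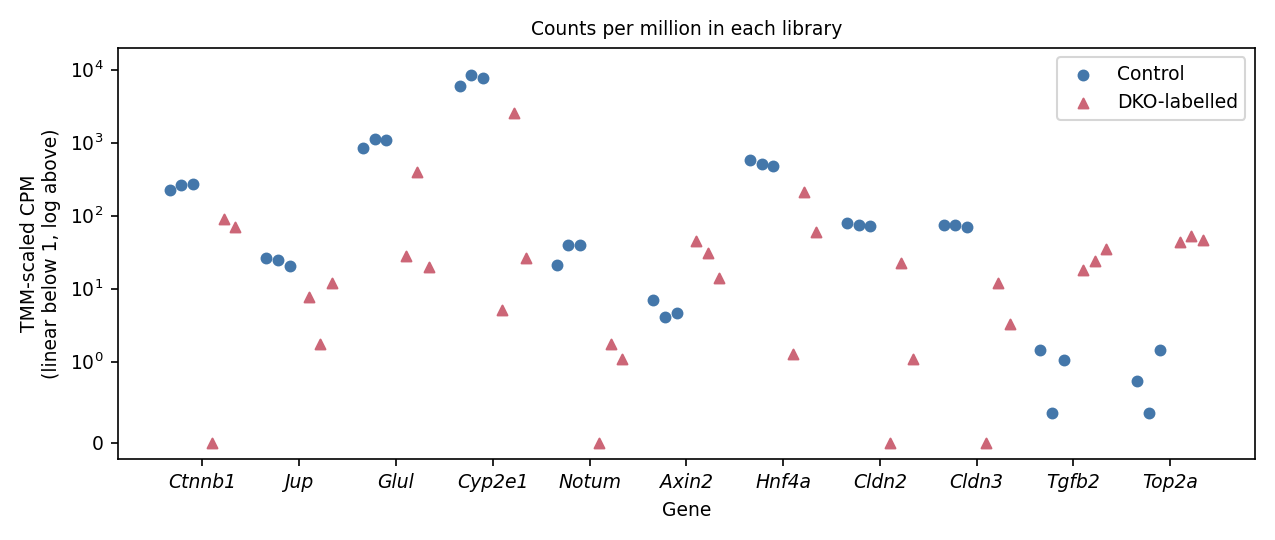
TMM-scaled CPM of named genes (horizontal axis) in each of the 3 Control (circles) and 3 DKO-labelled (triangles) libraries, on an axis that is linear below 1 and logarithmic above. Notum, Cldn2 and Cldn3 lay below Control in every DKO-labelled library and Tgfb2, Axin2 and Top2a above it. On the abundant-gene scale, which kept background reads, Ctnnb1, Jup, Glul and Hnf4a turned to positive log2 fold changes of 0.89, 3.90, 0.84 and 0.14.

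Junction genes moved in both directions. Cldn3, a sealing claudin, fell with a log2 fold change of -3.94 (SE 0.94, adjusted p = 0.00773), and the pore-forming claudin Cldn2 with one of -3.40 (SE 1.12, adjusted p = 0.0345). Both calls were lost on the abundant-gene scale and after background subtraction. The Cldn2 call was also lost without DKO replicate 3 (adjusted p = 0.0710) or without Control replicate 1, 2 or 3 (0.117, 0.0918 and 0.0961). Jam3, an adhesion molecule of tight junctions, rose with a log2 fold change of 4.12 (SE 0.81, adjusted p = 0.00279). Tjp1 had a log2 fold change of -0.23 (adjusted p = 0.745), which turned to 5.50 on the abundant-gene scale. The E-cadherin gene Cdh1 had one of -0.82 (adjusted p = 0.366), with an adjusted p of 0.0235 without DKO replicate 2. Of 22 tight junction genes 5 were higher and 3 lower, both over all genes and adjusted over the list alone. Of 15 adherens junction and desmosome genes 1 was higher and 3 lower, and 0 were called when adjusted over the list alone with edgeR. Of 27 polarity and trafficking genes 4 were higher and 6 lower, with 2 and 2 adjusted over the list alone. Among them Rab11fip1, an adaptor of recycling endosomes, rose by a log2 fold change of 3.03 (adjusted p = 0.0061), a call that background subtraction ended. Llgl1, a basolateral polarity protein, was at 0 in every DKO-labelled library and at least 5.37-fold lower, a call that the abundant-gene scale ended, with 1.94 reads expected there. The medians of these lists, -0.90, -1.11 and -1.48, lay within the matched random sets (matched medians -0.59, -1.22 and -1.18). They turned to 3.29, 3.67 and 3.00 on the abundant-gene scale. That scale kept background reads and shifted the median of all genes by 4.76, so a changed sign on it does not show a rise. Camera called none of these lists, with adjusted p of 0.248, 0.0672 and 0.0672.

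Of the hepatocyte gene groups, camera called the HNF4α and bile acid synthesis lists lower at its preset correlation but not at an estimated one (adjusted p = 0.815 for both). It did not call bile transport (adjusted p = 0.0672), FXR targets (0.0918) or keratin and surface genes (0.0672). HNF4α keeps the adult hepatocyte programme active, and Hnf4a itself had a log2 fold change of -2.55 (SE 1.39, adjusted p = 0.152), with an adjusted p of 0.0352 without DKO replicate 1 and 0.0417 without replicate 2. Its list of hepatocyte genes had a median of -2.73 and was called lower by camera (adjusted p = 0.000319). Of its 30 members 4 were lower and 0 higher, and 0 were called when adjusted over the list alone with edgeR. The median lay just below the matched random sets (-2.73 to -2.21) and turned to 0.57 on the abundant-gene scale. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the type of bile acid made, fell with a log2 fold change of -4.09 (SE 1.07, adjusted p = 0.0127), which turned to 0.81 on the abundant-gene scale and lost its call after background subtraction and with limma-voom (adjusted p = 0.0849 and 0.0627). The rate-limiting enzyme Cyp7a1 had one of -2.13 (adjusted p = 0.221), and the bile acid carriers Slc10a1 and Abcb11 had -3.03 (adjusted p = 0.105) and -2.54 (adjusted p = 0.0572). These carriers passed without DKO replicate 1 (adjusted p = 0.0247 and 0.00936) and without replicate 2 (0.0230 and 0.0174). DESeq2 called Hnf4a, Slc10a1, Abcb11 and the pericentral Glul lower. The conjugate exporter Abcc4 rose, with a log2 fold change of 4.31 (SE 0.80, adjusted p = 0.00195). The bile acid synthesis list had 2 of 15 members lower, and the bile transport list 1 of 16 higher. FXR targets had 2 of 8 lower and hepatocyte keratin and surface genes 1 of 7. Adjusted over the list alone, the counts were 0, 1, 2 and 1. The medians of these 4 lists lay within the matched random sets.

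Camera called 9 of 38 tested lists, all lower, and none of these calls held with an estimated correlation (adjusted p = 0.815). Beside the HNF4α list these were bile acid synthesis and periportal genes (both adjusted p = 0.0164), xenobiotic metabolism (0.0103) and genes higher in male liver (0.0266). The others were Kupffer cell markers, the endoplasmic reticulum stress response, lipogenesis and fatty acid oxidation (each 0.0422). All 9 calls were lost after background subtraction, and without DKO replicate 3 camera called 1 list. On the abundant-gene scale, which shifts all genes upward, camera called 12 lists, all lower than other genes. Except for the HNF4α list, the medians of the called lists lay within random sets matched on Control expression and expected background. For example, the periportal median was -2.49, with 1 of 17 genes lower and matched sets at -2.79 to -1.98. Members past the threshold were 2 lower of 19 for xenobiotic metabolism, 3 lower of 10 for the stress response, 3 lower and 1 higher of 15 for lipogenesis, and 1 each way of 18 for fatty acid oxidation. Adjusted over the list alone, these became 0, 3 lower, 1 each way and 0. Atf4, a transcription factor of the stress response, fell with a log2 fold change of -4.38 (SE 0.86, adjusted p = 0.00273), and lost its call on the abundant-gene scale. Directional fry, which asks whether the genes of a list move one way on balance, called 4 lists higher and 0 lower, and its mixed form called all 38.

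TGFβ genes had more members higher than lower, in shares close to those of all tested genes (4871 higher and 1992 lower of 15561). Tgfb2, a TGFβ ligand, rose from 0.95 ± 0.55 to 25.5 ± 8.49 CPM (SD, n = 3), a log2 fold change of 4.71 (SE 0.81, adjusted p = 0.00132). Tgfb1 had one of 1.13 (adjusted p = 0.453) and the receptor Tgfbr2 one of -1.58 (adjusted p = 0.257), which passed without DKO replicate 2 (0.00558). Itgb8 and Ltbp1, which take part in the activation and storage of latent TGFβ, rose by 6.84 (SE 0.99, adjusted p = 0.000783) and 4.26 (SE 0.69, adjusted p = 0.00104), the latter not after background subtraction. Itgb8 had 1, 2 and 1 Control counts and entered the test only through reads in the DKO-labelled libraries. All 1333 tested genes with 1 to 10 Control counts were called higher, so the Itgb8 call adds little support. Of 30 genes 10 were higher and 4 lower, also when adjusted over the list alone. The list median was 0.54, in the middle of matched random sets (matched median 0.58), and camera did not call it (adjusted p = 0.808). It turned to -1.26 after background subtraction.

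Col1a1, a chain of collagen 1, had a log2 fold change of 2.83 (SE 0.68, adjusted p = 0.00807), which missed the threshold without Control replicate 2 (0.0522) or 3 (0.0557) and after background subtraction. Extracellular matrix genes had 3 of 20 higher and 1 lower, and 2 higher when adjusted over the list alone, with a positive median of 0.77 but a downward camera direction (adjusted p = 0.820). Genes of epithelial-mesenchymal transition had 2 of 9 higher, also adjusted over the list alone, again with a positive median (0.05) and a downward direction (adjusted p = 0.778). The integrin Itga5 was one of them, with a log2 fold change of 2.67 (SE 0.58, adjusted p = 0.00448). Both medians lay within the matched sets (0.25 and -0.19), and both turned negative after background subtraction (-0.65 and -1.03).

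Some markers of cholangiocytes, T cells and dividing cells were higher, and 2 of 11 Kupffer cell markers lower, while camera did not call the cholangiocyte or proliferation lists. Sox9 and Pkhd1, known from bile duct cells, rose with log2 fold changes of 4.51 (SE 0.69, adjusted p = 0.000857) and 4.35 (SE 0.63, adjusted p = 0.000754), while Krt19 had one of 1.80 (adjusted p = 0.278). Of 13 cholangiocyte genes 7 were higher and 1 lower, and 7 and 2 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.238), and its median of 2.69 lay above matched sets, which reached 2.67. Cd3e, a T cell receptor chain, had 6, 2 and 0 counts in Control and 32, 31 and 75 in the DKO-labelled libraries. With so few Control counts, Cd3e entered the test only through reads in the DKO-labelled libraries. Itgam, of myeloid cells, rose with a log2 fold change of 6.17 (SE 0.74, adjusted p = 0.000686). The complement gene C1qc of Kupffer cells had 364, 243 and 228 counts in Control and 0 in every DKO-labelled library, at least 18.7-fold lower with TMM and 2.30-fold on the abundant-gene scale. The cyclin Ccnb2 and the topoisomerase Top2a rose with log2 fold changes of 7.23 (SE 0.86, adjusted p = 0.000682) and 5.77 (SE 0.76, adjusted p = 0.000717). Of 15 proliferation genes 7 were higher and 0 lower with edgeR, also adjusted over the list alone.

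The other lists of cell types gave smaller counts. Stellate cell genes had 3 of 14 higher and 1 lower, with a positive median (0.44) and a downward camera direction (adjusted p = 0.740). Sinusoidal endothelial genes had 2 of 13 each way, Kupffer genes 2 of 11 lower, monocyte and macrophage genes 3 of 7 higher, and B cell genes 2 of 4 higher and 1 lower. Adjusted over the list alone, these were 2 higher and 1 lower, 2 each way, 2 lower, 3 higher and 1 lower, and 3 higher and 1 lower. Of 12 T and NK cell genes 3 were tested and all 3 were higher, as were 3 of the 4 tested of 12 adipose and muscle genes and both tested of 8 neutrophil genes. Genes of low Control counts enter the test only through reads in the DKO-labelled libraries, and 4 of the 9 untested T and NK cell genes had Control counts, of up to 23 in a library, and 0 reads in the DKO-labelled ones. Erythroid genes had 0 of 5 called by edgeR, and none of 12 pancreas genes passed the count filter. Proliferation, T and NK cell, fetal and tumour, and adipose and muscle genes were the lists that fry called higher (adjusted p = 0.0313, 0.0163, 0.0163 and 0.0163), and camera called none of them (0.191, 0.0764, 0.0992 and 0.174). These lists had low Control levels, with medians of 1.72, 0.213, 1.25 and 0.0625 CPM, and their medians lay within the matched random sets.

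Among the remaining lists, acute phase genes had 2 of 14 higher and 1 lower, chemokine and cytokine genes 2 of 11 higher, and antioxidant genes of the NRF2 pathway 1 of 13 higher and 2 lower. YAP targets had 4 of 13 higher and 1 lower, fetal and tumour genes 4 of 7 higher, and cholesterol synthesis genes 2 of 21 lower. Adjusted over the list alone, the counts differed for acute phase genes (1 each way) and cholesterol synthesis genes (1 lower). Il6, an inflammatory cytokine, was at 0 in Control with 12, 3 and 16 reads in the DKO-labelled libraries, at least 141-fold higher. It is among the 1459 tested genes without a Control count, all of which were called higher. Nsdhl, of cholesterol synthesis, fell with a log2 fold change of -4.22 (SE 0.79, adjusted p = 0.00196) and lost its call on the abundant-gene scale. Camera called none of these 6 lists (adjusted p = 0.0918, 0.820, 0.196, 0.820, 0.0992 and 0.0522). Lists kept as checks gave 1 gene each way of 5 for sex chromosome genes, 1 lower of 15 for male liver genes and 1 each way of 5 for female liver genes (0 for male liver genes when adjusted over the list alone). The sex chromosome list had a positive median (0.02) and mean (0.99) with a downward camera direction, and the female liver list a negative median (-1.33) with a positive mean (0.37). Immediate early genes had 3 each way of 10 and clock genes 3 each way of 16, with 3 higher and 4 lower immediate early genes when adjusted over the list alone. Xist had 0 to 1 counts in Control and 1, 0 and 6 in the DKO-labelled libraries, and the Y-linked Ddx3y had 937, 725, 630, 29, 80 and 30, so all 6 libraries carried Y-linked reads. Kdm5d had 6, 8 and 8 counts in the DKO-labelled libraries, Eif2s3y 9, 22 and 34, and Uty 6, 20 and 17, each with at least 140 in every Control library, and Tsix had at most 8 in any library.

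Relative to the abundant liver genes of the same library, the DKO-labelled libraries differed from each other. This comparison was chosen after the data were examined, describes single libraries without replication, and uses the 13 lists with at least 5 members above 3000 Control counts, after background subtraction. In DKO replicate 2 all 13 list medians lay within the middle 95% of 10000 random sets matched on Control expression, and the pericentral median was -0.10 in log2. In DKO replicate 3 the pericentral, xenobiotic and bile transport medians lay below matched sets, at -3.38, -1.49 and -1.42, and the acute phase median lay above them, at 1.86. Without background subtraction these medians were -1.59, -0.89, 0.25 and 1.89, and bile transport lay within its matched sets, while the bile acid synthesis, HNF4α and male liver medians, at 0.07, -0.18 and -0.71, now lay below theirs. Cyp2e1 had 24 reads there where 448 would match its Control proportion, and Cyp1a2 had 2 where 44.5 would. The acute phase gene Saa1 had 833 reads where 5.66 would match. The haptoglobin gene Hp had 739 where 208 would. Among the Control libraries themselves, 4, 5 and 1 of the 13 medians lay outside their matched sets. The pericentral, xenobiotic and acute phase lists were among these in Control replicates 1 and 2. The acute phase median lay above its matched sets in Control replicate 1 (0.19) and below them in Control replicate 2 (-0.23). In DKO replicate 1 all 13 medians lay within matched sets, at a depth of 0.0465% of the Control level for the abundant genes against 1.88% and 0.550% in replicates 2 and 3. Saa1 shares sequence with its neighbouring paralogs, so its count is uncertain.

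**Figure D4:**
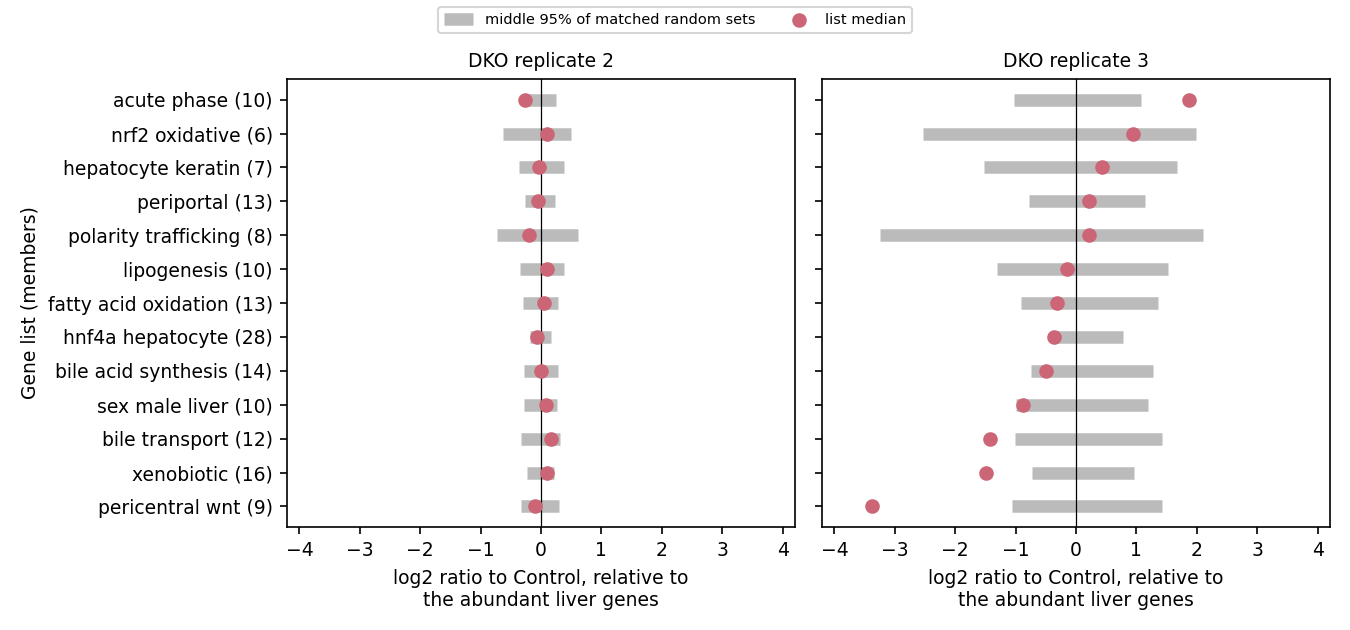
Median log2 ratio to the Control mean, relative to the abundant liver genes of the library (horizontal axis, points), of 13 gene lists (vertical axis, members in brackets) in DKO replicate 2 (left) and DKO replicate 3 (right). Grey bars give the middle 95% of 10000 random sets matched on Control expression, and in replicate 3 the pericentral median was -3.38 (-1.59 without background subtraction) and the acute phase median 1.86, while in replicate 2 all medians lay on the bars.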

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

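The test of genomic DNA was chosen after the near-silent genes had been looked at, and the other tests in this part were set before their results were seen. Reads outside the gene comparisons were higher in the DKO-labelled libraries than in any Control library. Uniquely aligned reads outside genes made up 73.7%, 65.3% and 61.0% of reads in DKO replicates 1, 2 and 3, against 37.8% to 40.6% in Control. Receptor genes of the nose had a summed 1789, 1084 and 823 CPM, against 9.10 to 14.2 in Control.

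More genes were higher than lower in the DKO-labelled libraries, and reads unrelated to expression in liver may account for a large part of this. Near-silent genes on the X chromosome had 0.468, 0.443 and 0.471 times the reads per kb of autosomal ones at equal GC content in DKO replicates 1, 2 and 3 (median 0.468, bootstrap intervals within 0.322 to 0.581), against 1.34, 0.896 and 0.994 in Control, which is in line with genomic DNA of male mice. Higher genes outside the near-silent set had a median of 3.47 times the reads expected from background and scaled Control expression, between the bounds set for and against background as their source, and it stays open because these genes were selected for high counts and the background is clumped (66.0% of near-silent genes had no read in DKO replicate 1, where evenly spread reads would leave 14.8%). The pooled markers of other cell types lay at percentile 83.3 of matched sets, which by the bound set beforehand counts against more cells of those types; that bound was set aside after the result was seen, because the lists went both ways (medians 2.69 for cholangiocytes and -1.89 for Kupffer cells), so this stays open. The real split called 6863 genes and the highest other split 0 (1 of 10 splits as large), and 10 splits are too few for a share under 0.05.

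For the gene lists, camera called 9 in the real split and up to 16 in another, with 4 of the 10 splits giving as many, and 10 splits are too few for a share under 0.05.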

How the results depend on the processing

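The settings scaled on abundant liver genes, with background subtracted, restricted to at least 50 CPM in Control, without mitochondrial and ribosomal-RNA-like genes, and with single DKO-labelled libraries were chosen after seeing the data. The gene-assigned share was 30.1 percentage points lower in the DKO-labelled libraries and kept its direction without any library. Of 79 named genes past the threshold, 36 kept direction and call in every setting that gave a value, and 11 reversed in some setting. The lower genes among the 36 were C1qc, Dgat1, Gstm4, Prnp, Spns2 and Srsf4, each at 0 in every DKO-labelled library. The higher ones include genes with at most 10 Control counts, such as Il6, Jph4 and Itgb8. For such genes the counts or the count filter fix the direction, so keeping the call adds little support. Where neither fit passed, a change of sign was counted as no change. Except where fewer libraries or genes explain it, the cause was not tested.

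Against 6863 genes, calls numbered 16127 without a filter, 4569 at an adjusted p of 0.01, 0 at 50 CPM in Control (523 at an unadjusted p under 0.05 in edgeR), and 10811 and 11637 with DKO replicate 1 or 3 alone. Leaving out a library gave 4710 to 9728. Against 9 gene lists, camera called 14 with DESeq2's size factors, upper-quartile normalization or the filter of 1 CPM, 21 without a filter, 0 with background subtracted, 2 at 50 CPM in Control, 15 with DKO replicate 3 alone, 1 to 14 without a library and 0 with an estimated correlation. Fry called 4 lists by direction and 38 in its mixed form.

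Ctnnb1 passed the threshold without a filter (-2.82), without DKO replicate 1, and with DKO replicate 1, 2 or 3 alone (-14.10, -1.50 and -2.04). The lone library is assumed to vary like the Control libraries, and -14.10 is a fitted value over 0 reads, no bound, where 1.32 reads would match the Control proportion. Leaving out a library gave -3.004 to -1.81. Jup passed with DESeq2 (-1.65), without a filter (-1.96), with background subtracted (-10.13), without DKO replicate 1, and with DKO replicate 1, 2 or 3 alone (-1.57, -3.76 and -1.17). Its reads lay below expected background, so -10.13 is a fitted value over 0 reads and the values of single libraries carry little weight. Leaving out a library gave -1.82 to -1.42. The abundant-gene scale kept background reads and shifted the median of all genes by 4.76, so reversals on it do not show rises. On that scale Jup reversed to 3.90. So did Acadl (1.04), Akr1d1 (2.87), Apoa4 (0.81), Asgr2 (1.66), Cyp3a13 (1.65), Cyp8b1 (0.81), F7 (0.87), Gls2 (1.26), Klb (0.66), Nr1i2 (3.14) and Tjp1 (5.50). At 50 CPM in Control, Akr1d1 (0.32) and Nr1i2 (0.45) reversed, and with DKO replicate 2 alone Ppargc1a did (-1.89).

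With replicate number as a block, 6322 genes and 13 lists were called, 12 named genes lost their call and Cyp7a1 gained one. Libraries of the same number shared deviations weakly (correlations of 0.122, 0.0844 and -0.0179 across 13529 genes), and not every library correlated best with its own number, so the numbers were not taken as pairs.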

Other observations

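The tests of the carry-over of Control reads or RNA, of catenin transcripts, of background and of the loss of the pericentral programme were chosen after the results were seen, and the test of length and GC content before. Random gene sets matched on Control expression and expected background gave a further view of the 38 lists in all 6 libraries. The pericentral and HNF4α lists lay below their matched sets. The cholangiocyte list, the monocyte and macrophage list (median 1.66, matched median -0.26) and the erythroid list (median -0.66, matched median -2.15) lay above. The other 33 lists lay within. Members of a list can move together, with an estimated correlation of 0.834 for the HNF4α list and 0.871 for the erythroid list. Random sets do not carry this, so their ranges can be too narrow for a list. The 38 comparisons were not adjusted for their number, and the HNF4α and cholangiocyte lists lay only just outside. Near-silent genes with reads in 1 DKO-labelled library tended to have them in the others, with Spearman correlations across 8600 genes of 0.577, 0.623 and 0.610. These used raw counts, so differences in exonic length and GC content can by themselves give a positive correlation. Genes are also not independent replicates.

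In the library labelled DKO replicate 2 the liver transcripts kept Control-like proportions, with 99.4% of the 163 abundant genes within a 2-fold range of the library's scale. Carry-over of sequenced Control reads with background alone is argued against: at the smallest expectation that any mixture of the Control libraries allows, with no background counted, 63 of 1523 genes expecting at least 20 reads lay below the 0.1% Poisson limit, where counting error would give 1.52. Carry-over of Control RNA or cDNA before amplification stays open, as does RNA of another liver, which was not tested. The best mixture left a chi-square of 17.6 per gene, where Control replicates 1, 2 and 3 thinned to the same depth gave 20.4, 4.13 and 5.69 against the others, and at 5 to 10 expected reads it was 6.51 against 1.81 for Control replicate 1, with 8 of 100 genes at 0 reads where 0.0756 would be, but the scatter from uneven amplification was not measured. Ctnnb1 stood at 0.834 of its Control proportion (95% counting interval 0.587 to 1.14). A liver that kept Ctnnb1 transcripts, by its genotype or by a wrong label, may therefore account for the pattern. The 1 Jup read, against 5.05 expected at the Control proportion and 9.34 from background, gives no sign of kept Jup. Reads from undeleted exons or from cells other than hepatocytes are counted here too, so the Ctnnb1 value does not decide about the label.

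In the library labelled DKO replicate 3 the pericentral transcripts were low against other liver transcripts. Background reads add counts, and 8 of 9 abundant pericentral genes had fewer reads than their Control proportion without any subtraction (median log2 ratio -1.59, and -3.38 with it), which argues against them. A loss of transcripts that follows the fitted trend with length, GC content and Control level is argued against as well. The median was -3.58 after that trend was removed (-2.10 without subtraction). The trend explained only 8.41% of the variance, so its removal could move the median little. A loss by length or GC content of another form was not tested. A loss of the β-catenin programme of pericentral hepatocytes stays open. Percentile 0.02 of matched sets restates the low median, and Control replicate 2 reached 99.93 in the same list. Ctnnb1 stood at 2.97 times its Control proportion (2.02 to 4.11). That interval covers counting error only, the background is clumped, and abundant genes scattered more widely here than in DKO replicate 2. Reads from undeleted exons or from cells other than hepatocytes are counted too. The Ctnnb1 value therefore cannot decide for or against a loss. An inflammatory state, with Saa1 at 833 reads, stays open and was not tested.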
